A study of Mus musculus with 2 samples.

How the data were processed

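Chromatin accessibility was measured by ATAC-seq in forebrain of mouse embryos at day 12.5. ATAC-seq uses a transposase that inserts sequencing adapters into DNA that is not covered by nucleosomes, so that reads pile up at accessible regulatory elements. The labels give 1 group with 2 biological replicates of mixed sex. Replicate 1 was pooled from 120 embryos and replicate 2 from 68 embryos. No treated, mutant or other-stage samples were analysed here, so the comparisons were between replicates, between gene lists and between positions in the genome.

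The files used were peak lists on the mm10 build, per the labels. For each library the authors deposited peaks found again in random splits of its own reads (pseudoreplicated peaks) and the subset that passed an irreproducible discovery rate (IDR) threshold. For the pooled reads they deposited the same kinds of lists, peaks of the pool found in both libraries (replicated peaks), and peaks that passed the IDR threshold between the true replicates (the conservative set). The aligner, the peak caller, the IDR threshold and their versions are not given in the sources used here. Each deposited peak carries a signal value, the height of its summit relative to background. Each also carries the authors' −log10 p and −log10 q and a score that is capped; the ranked lists add −log10 values of the IDR. These are the authors' own values per peak, and they were used to describe, rank and filter peaks. The ranked list of the true replicates also has 8 columns of values per replicate, and these were not used because the columns do not name the replicate. The lowest score in the conservative set was 540, and 5.03% of its peaks had a q above 0.01. Of these 3233 peaks, 3204 lay in intervals that also held a peak with a q of 0.01 or less.

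Overlapping peaks were merged into intervals, because the lists give a separate entry for each summit of a region. The conservative set of intervals was the main set. An interval was called a promoter interval when it lay within 1 kb of a transcription start site of a protein-coding or long noncoding gene of the GENCODE M21 basic annotation, and distal otherwise. Each distal interval was assigned to the nearest protein-coding start site within 500 kb. Nearest genes are a convention and do not show which gene an element acts on. Shares of summits by genomic class were set against 1e+06 random positions of the genome.

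The files used here give no read totals. In the pseudoreplicated lists of both libraries and of the pool, signal and −log10 p fitted the relation of a whole number of tags at the summit to a local background under a Poisson model, with 100% of summits within 0.02 of a whole number. This gave the tags and the background at each summit, and the genome-wide background per position of each library, on the scale of the caller. The number of reads remained unknown.

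Overlap between replicates required 1 bp, and its expected share came from 100 circular shifts within chromosomes. Strength in the replicates was compared over intervals of the replicated set that both pseudoreplicated lists overlapped, with the strongest overlapping value of each. Correlations were across peaks, which are not independent replicates, and carry no p-value. Exact binomial 95% intervals of shares, and intervals of ratios of shares, cover counting error over peaks only.

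Before the data were examined, 18 gene lists with 292 genes and 27 sequence motifs were fixed, along with the tests and most of the alternatives. The lists covered pallial, subpallial, diencephalic, neural progenitor, neuronal, mid- and hindbrain, Hox, endothelial, myeloid, erythroid, mesenchymal, surface ectoderm, cardiac, hepatic, skeletal muscle, pluripotency, mature glial and housekeeping genes. Distal intervals per gene were compared with 10000 random lists of the same size, matched in 10 bins of territory, the span between neighbouring start sites. This two-sided permutation test cannot give a p below 0.0001. Promoter accessibility of a list was compared with all other protein-coding genes by a two-sided Fisher's exact test. Both kinds of p were adjusted over the 18 lists by the Benjamini-Hochberg method, and an adjusted p below 0.05 was called. The replicate difference of a list was the median log2 ratio of signal over its shared peaks, centred on all shared peaks. It was placed among 10000 random peak sets matched on mean signal, called outside when beyond the 2.5th or 97.5th percentile, and given no p-value; lists with fewer than 3 shared peaks were not tested. These tests describe the peak sets of 2 libraries, and p-values over genes do not measure the spread between embryos.

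Motif matches on either strand were counted within 100 bp of distal summits and in windows of the same length 2 kb to either side and outside all peaks, in the GRCm38.p6 sequence. A ratio of shares of at least 1.5 was called, and a ratio against 0 control matches was computed with 3 matches in its place as a lower bound. Promoters were called CpG-rich when the observed over expected CpG frequency within 500 bp of the start site was at least 0.6. Intervals were aligned to the mitochondrial genome with BLAST 2.17.0 and called matching at 90% identity over at least 100 bp. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and samtools 1.23.1, and figures were drawn with matplotlib 3.10.9.

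Genes were named by a rule. It took the 3 genes of each list with the most distal intervals, up to 3 of each list with neither a distal nor a promoter interval, and the 10 genes with the most distal intervals genome-wide. It also took the 10 strongest distal and 5 strongest promoter intervals by signal, and the 5 strongest intervals found in 1 replicate alone. Other genes named below were chosen after their values were seen.

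The steps were tested on simulated data. Tags were recovered at 100% of 5000 simulated summits, and 4.28% of summits simulated without whole numbers passed by chance. Over 21911 genes, 4.5% of unchanged simulated lists had a permutation p under 0.05. The same unadjusted threshold was passed by 90% of simulated lists with a 3-fold change and 40% of those with a 2-fold change. These shares rest on few simulated lists and on p before adjustment. The power of the adjusted test used on the data was therefore not measured. The motif scan found 100% of the CTCF matches planted in a part of 2000 simulated windows; other motifs were not planted. Alternatives covered the peak set, the promoter window, the overlap rule, the assignment distance, medians in place of means, the motif window, the control windows and leaving out each replicate, for which the IDR set of the other library was used alone.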

Results

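Accessible chromatin was mapped in 2 pools of whole forebrain from day 12.5 mouse embryos, a stage at which the pallium (future cortex), the ganglionic eminences of the subpallium and the diencephalon hold dividing progenitors and young neurons. The conservative set held 64214 peaks in 22747 merged intervals that covered 24.6 Mb, with a median width of 1087 bp. Of these intervals, 12737 lay at promoters and 10010 were distal. The number of reads per library was unknown. The genome-wide background recovered from the peak values was 5.99 tags per position in replicate 1 and 6.10 in replicate 2.

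Distal intervals were compared between gene lists to ask which genes of the developing forebrain lay among accessible elements. Regulators of neural progenitors had the most, with 95 distal intervals over 20 genes. Sox9, which specifies neural stem cells and later glia, had 13 (chromosome 11, 112782224 to 112787760). Sox2, which maintains the progenitor state, had 12 (chromosome 3, 34650405 to 34652461), and the nuclear receptor gene Nr2f2 had 11 (chromosome 7, 70351944 to 70366735). Genes of postmitotic neurons had 63 over 18 genes, led by the RNA-binding protein gene Celf4 with 17, the neuronal zinc finger gene Myt1l with 13 and the growth cone gene Gap43 with 7. The subpallial list had 58 over 20 genes, led by the proneural gene Ascl1 with 9, Sp8 with 8 and Isl1 with 8; Sp8 and Isl1 encode transcription factors of the ganglionic eminences. Gad1, which encodes a GABA-synthesising enzyme, was the member of that list with neither a distal nor a promoter interval. Of the 3 distal intervals nearest to its paralog Gad2, 2 matched the mitochondrial genome. The pallial list had 47 over 18 genes, led by Nfib with 8, Nfia with 7 and Otx1 with 4, all transcription factor genes of the developing cortex. In replicate 2 alone, which had fewer distal intervals, Nfib had 1, Nfia 2, Sp8 2 and Isl1 3, against 9, 6, 7 and 8 in replicate 1 alone. Sox2 and Nr2f2 had 4 each there, against 14 and 11, and Ascl1 had 5 against 6. Myt1l had 7 against 11, Gap43 4 against 7 and Otx1 2 against 5.

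The mean per gene was 4.75 in the neural progenitor list against 1.06 in matched random lists (ratio 4.49, adjusted permutation p = 0.00090). It was 2.90 against 0.860 in the subpallial list (ratio 3.37, adjusted permutation p = 0.00090). For these lists the unadjusted permutation p was 0.0001, the smallest that the permutations can give. The neuronal mean was 3.50 against 1.15 (ratio 3.05, adjusted permutation p = 0.0012) and the pallial mean 2.61 against 1.01 (ratio 2.57, adjusted permutation p = 0.0027). In replicate 2 alone the pallial mean was 0.944 against 0.434 and did not pass (adjusted permutation p = 0.092). With the stronger-signal intervals only, the pallial and subpallial lists did not pass (adjusted permutation p = 1 and 0.15). Intervals with a stronger signal lay more often at promoters, so fewer distal intervals remained in this setting. It left Nfib with 2, Nfia with 1, Otx1 with 0, Ascl1 with 1, Sp8 with 2 and Isl1 with 3. The difference per gene from random lists was 0.0061 in the pallial and 0.32 in the subpallial list. Whether the calls were lost through the lower counts was not tested.

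The diencephalic list did not pass, with 2.12 intervals per gene against 1.10 (adjusted permutation p = 0.075). It passed in the larger replicated set and by the median per gene (adjusted permutation p = 0.0029 and 0.016). Its leading members were Tcf7l2 with 7, a thalamic regulator in the Wnt pathway, Lhx5 with 5 and the hypothalamic regulator Sim1 with 4, while the hypothalamic gene Nkx2-4 had none. In replicate 1 and replicate 2 alone Tcf7l2 had 9 and 4, Lhx5 3 and 1, Sim1 4 and 3 and Nkx2-4 2 and 0. Transcription factors of the midbrain, hindbrain and spinal cord had 1.22 per gene against 0.923 (adjusted permutation p = 0.67). Pax5, Pax7 and En1, which pattern the midbrain and its borders, had 3 each, and Gata2 had neither a distal nor a promoter interval. In replicate 1 and replicate 2 alone Pax5 had 2 and 3, Pax7 1 and 1 and En1 1 and 0. The strongest interval assigned to Pax5 reached a signal of 16.1.

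No list of another tissue passed. For the Hox, myeloid, erythroid, hepatic and skeletal muscle lists, the range of matched random lists began at 0 intervals per gene. The test could therefore not call fewer intervals in these lists. The Hox list had the fewest possible, and its unadjusted permutation p was 0.24. The 24 Hox genes, which pattern the body axis behind the forebrain, had 0 distal intervals against 0.0949 per gene in random lists, whose territories are as small (adjusted permutation p = 0.48). In replicate 1 alone they had 0.0833 per gene against 0.0865, and in replicate 2 alone 0 against 0.0492. Myeloid genes had 0.714 per gene against 0.326 (adjusted permutation p = 0.18), and 6 of their 10 intervals were assigned to Ptprc, which encodes the leukocyte protein CD45. Laptm5 had 3 and C1qa had 1, and 10 of the 14 myeloid genes, among them Aif1, C1qb and Cd68, had neither kind of interval. In replicate 1 and replicate 2 alone Ptprc had 4 and 2, Laptm5 2 and 1 and C1qb 1 and 1. Endothelial genes had 0.571 against 0.845 (adjusted permutation p = 0.71), with 2 at Cdh5, 1 each at Emcn and Sox17 and none of either kind at Cldn5, Esam and Flt1. Mesenchymal genes had 0.471 against 1.05 (adjusted permutation p = 0.34), with 2 at Foxc1 and 1 each at Dcn and Col1a1. The replicates alone gave 2 and 1 at Cdh5, 3 and 1 at Foxc1, 2 and 1 at Dcn and 0 and 1 at Col1a1. Erythroid genes had 0.133 against 0.167 (adjusted permutation p = 0.97), and the globin gene Hba-a1 and its regulator Gata1 had neither kind.

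Hepatic genes had 0.0714 per gene against 0.317 (adjusted permutation p = 0.53), and the serum protein genes Alb, Afp and Ahsg had neither kind of interval. Surface ectoderm had 0.333 against 0.566, cardiac genes 0.50 against 0.544 and skeletal muscle 0.214 against 0.248. Pluripotency genes had 0.50 against 0.607 and mature glial genes 0.50 against 0.451. The adjusted permutation p of these 5 lists lay between 0.71 and 1. Epcam and Krt8 of surface ectoderm, and Chrna1 and Acta1 of muscle, had 1 distal interval each. The heart regulators Gata4, Hand2 and Tbx20 had 2 each, the pluripotency gene Esrrb had 3 and Nanog 1, and the myelin genes Mobp and Mog had 2 and 1. These counts rest on few intervals: in replicate 1 and replicate 2 alone Gata4 had 0 and 0, Hand2 2 and 0, Tbx20 1 and 0, and Acta1 1 and 0. Esrrb had 1 and 1, Nanog 2 and 1 and Mobp 1 and 1. Housekeeping genes had 0.50 against 0.195 (adjusted permutation p = 0.10), led by the ubiquitin gene Ubc and the elongation factor gene Eef1a1 with 3 each (3 and 4, and 4 and 2, in the replicates alone). They passed in replicate 1 alone (0.556 against 0.182, adjusted permutation p = 0.046) and in replicate 2 alone (0.444 against 0.0954, adjusted permutation p = 0.021).

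**Figure D1:**
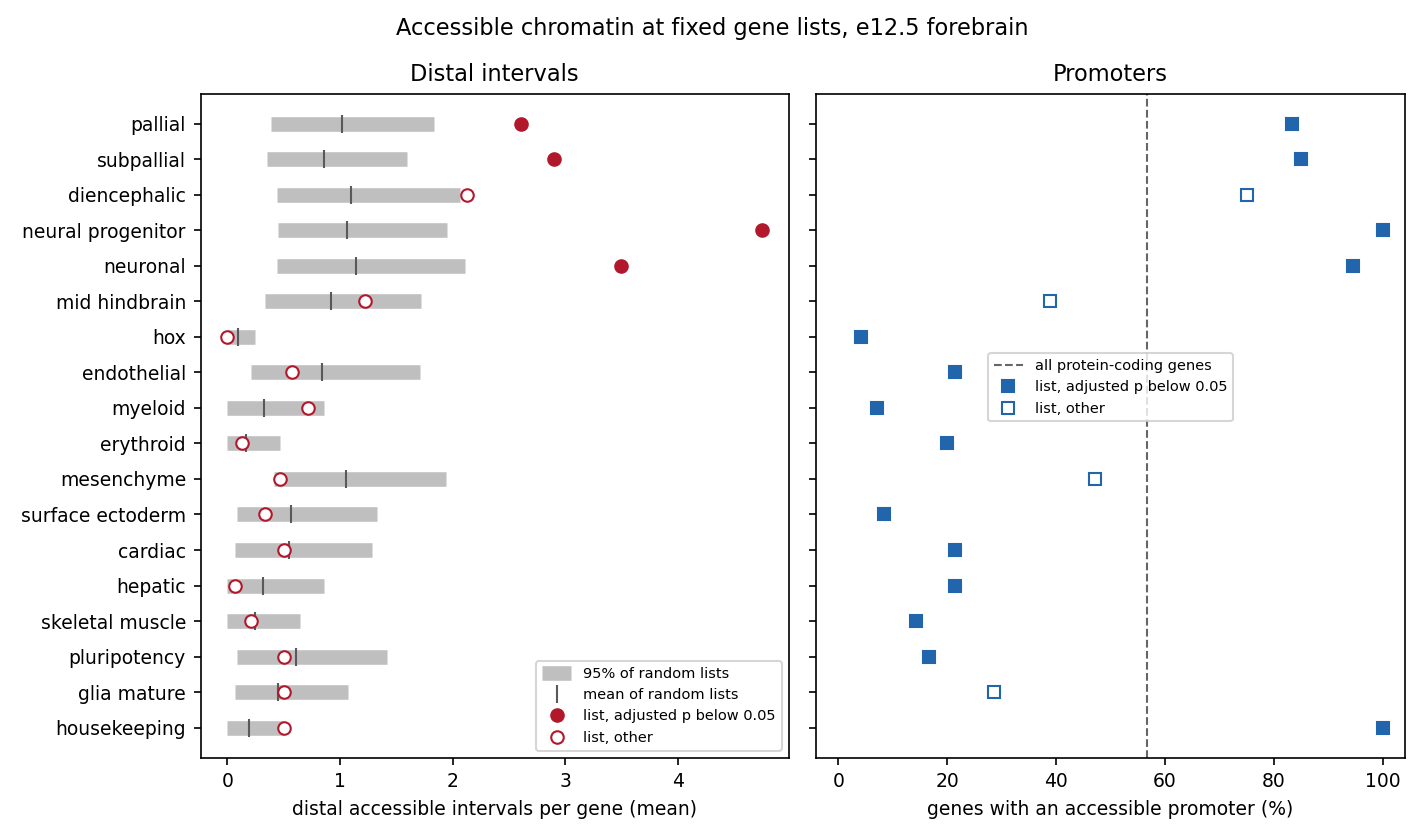
Left, mean number of distal accessible intervals per gene for each of the 18 fixed gene lists (points) with the mean (ticks) and 95% range (grey bars) of matched random lists; right, share of each list's genes with an accessible promoter in percent (squares) and the share of all protein-coding genes (dashed line, 56.8%). Filled symbols have an adjusted p below 0.05, and the neural progenitor list lies highest on the left at 4.75 per gene.

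Over the whole genome, 9673 distal intervals were assigned to a gene, at a median distance of 43.5 kb. Of 21911 protein-coding genes, 76.2% had none and 32 had 10 or more. The 10 genes with the most were led by Rapgef5, a guanine nucleotide exchange factor gene, with 19 and Auts2, linked to neurodevelopmental disorders, with 18. Celf4 had 17, and the synaptic adhesion gene Nrxn3, the zinc finger gene Zfp608 and the neuronal transcription factor gene Mef2c had 16 each. The Notch pathway corepressor gene Tle3 had 14, and Myt1l, Sox9 and Gm26897 had 13 each. At Sox9 the elements lay on both sides of the gene, and the strongest stood at 112501665 to 112502523 with a signal of 13.0. The sets of replicate 1 and replicate 2 alone gave 15 and 10 distal intervals at Rapgef5, 17 and 6 at Auts2, 12 and 6 at Celf4 and 14 and 6 at Sox9. They gave 17 and 12 at Zfp608, 15 and 11 at Mef2c, 13 and 7 at Nrxn3 and at Tle3 and 11 and 6 at Gm26897, so the order of these genes differed between replicates. These counts were not adjusted for territory, which was 1649 kb at Auts2 and 157.9 kb at Ascl1.

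**Figure D2:**
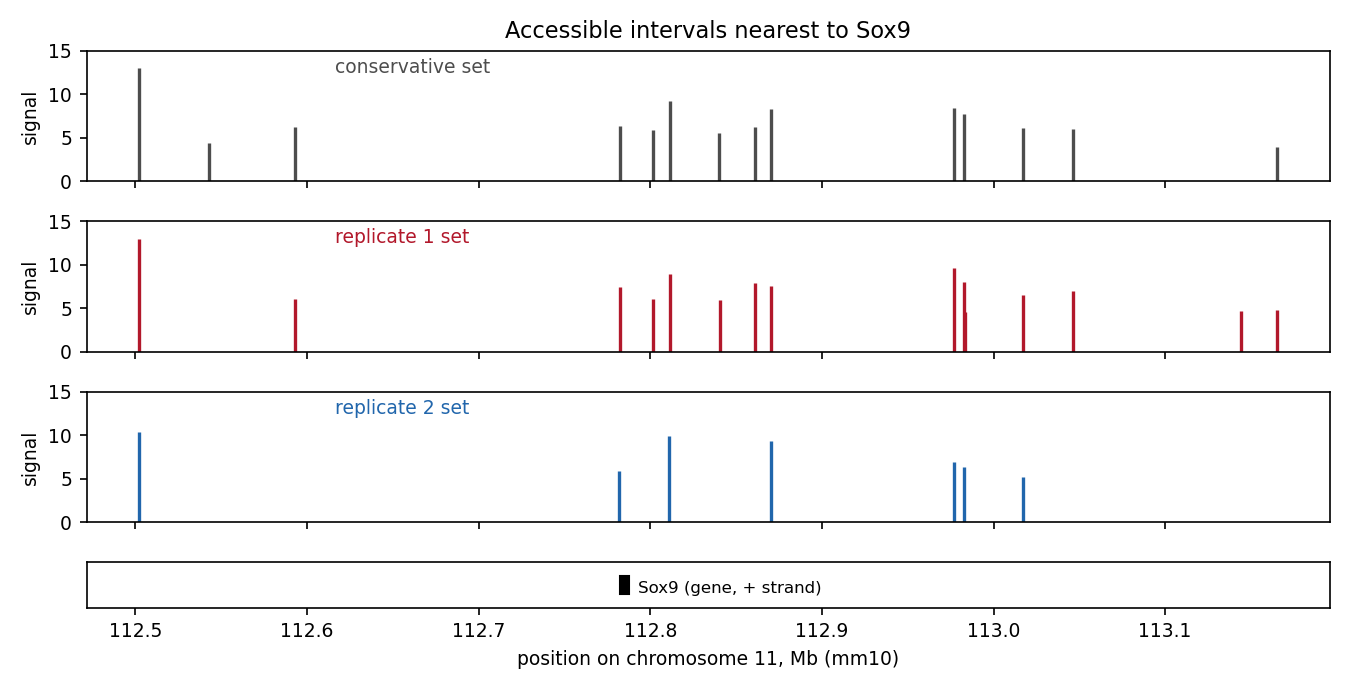
Signal of the accessible intervals assigned to Sox9 (vertical lines at interval midpoints) against position on chromosome 11 in Mb (mm10), in the conservative set, replicate 1 and replicate 2; the gene is the black box. The conservative set shows 13 distal intervals and 1 at the promoter, with the strongest upstream of the gene at a signal of 13.0.

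Promoters were compared between the same lists. All 20 neural progenitor genes and all 18 housekeeping genes had an accessible promoter, and 17 of 18 neuronal genes did, against 56.8% of all protein-coding genes (adjusted Fisher exact p = 0.00012, 0.00026 and 0.0021). The subpallial list had 17 of 20 and the pallial list 15 of 18 (adjusted Fisher exact p = 0.017 and 0.038). Among Hox genes 1 of 24 had one, the promoter of the anterior gene Hoxa1 (adjusted Fisher exact p = 1.05e-06); in the set of either replicate alone 0 of 24 did. Myeloid genes had 1 of 14, surface ectoderm 1 of 12, skeletal muscle 2 of 14, pluripotency 2 of 12 and erythroid genes 3 of 15 (adjusted Fisher exact p = 0.00069, 0.0021, 0.0045, 0.014 and 0.014). Endothelial, cardiac and hepatic genes had 3 of 14 each (adjusted Fisher exact p = 0.017 for each list).

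So 14 of 18 lists passed, 5 with more and 9 with fewer accessible promoters than other genes. The diencephalic list with 12 of 16, the mid- and hindbrain list with 7 of 18, the mesenchymal list with 8 of 17 and the mature glial list with 4 of 14 did not pass (adjusted Fisher exact p = 0.22, 0.17, 0.47 and 0.066). The pallial call ended in replicate 1 alone and in replicate 2 alone (14 and 9 of 18 genes, adjusted Fisher exact p = 0.083 and 1). So did the subpallial call (15 of 20 genes in each, adjusted Fisher exact p = 0.14 and 0.051), and the cardiac call ended in replicate 1 alone (5 of 14, adjusted Fisher exact p = 0.20). In replicate 2 alone the mesenchymal and mature glial lists passed with 4 of 17 and 1 of 14 genes (adjusted Fisher exact p = 0.038 and 0.0013). In the larger replicated set the endothelial, surface ectoderm and cardiac calls ended, with differences of -13.68, -13.68 and -20.8 percentage points (adjusted Fisher exact p = 0.32, 0.39 and 0.19), and the mature glial list passed (adjusted Fisher exact p = 0.018). The mature glial list also passed with promoters within 2.5 kb (-29.5 points, adjusted Fisher exact p = 0.038).

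CpG-rich promoters were accessible in 91.3% of genes and others in 21.3%. Among CpG-rich promoters alone, a comparison chosen after seeing the data, 5 lists passed, all with fewer. These were Hox with 1 of 16, mid- and hindbrain with 7 of 16, surface ectoderm with 1 of 5, endothelial with 2 of 6 and pluripotency with 1 of 4 (adjusted Fisher exact p = 2.8e-14, 1.6e-05, 0.0016, 0.0033 and 0.0088). More accessible promoters could not be shown there: neural progenitor and housekeeping genes had 17 of 17 each, the most possible in the largest lists, and did not pass (adjusted Fisher exact p = 0.54). The pallial list had 14 of 14, also the most possible. The neuronal list had 11 of 12 (91.7%) and the subpallial list 14 of 17 (82.4%), against 91.3% of other genes. The neuronal excess was thus nearly gone there. The subpallial list lay below other genes but did not pass (adjusted Fisher exact p = 0.29). Among promoters that were not CpG-rich, accessible ones were 6 of 6 neuronal, 3 of 3 subpallial, 3 of 3 neural progenitor, 1 of 1 housekeeping and 1 of 4 pallial, which was not tested.

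By position of the summit, 54.4% of conservative intervals lay within 1 kb of a start site (95% interval 53.8 to 55.1), against 2.72% of the genome. Introns held 22.1%, intergenic sequence 21.1% and exons 2.38%, against 40.3%, 54.3% and 2.69% of the genome. The promoter share was 92.6% in the strongest of 10 equal groups by signal and 26.6% in the ninth. It was 52.6% in replicate 1 and 70.1% in replicate 2. The strongest promoter intervals lay at Zfp960 (signal 23.5), 6720489N17Rik (22.9), Tmem218 (22.9), the threonyl-tRNA synthetase gene Tars (21.7) and 2610008E11Rik (21.6).

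The strongest distal interval by signal lay 35.5 kb from Pak3, a kinase gene, on chromosome X (143482934 to 143483180, intergenic) with a signal of 54.5. The next were nearest to Abcb11 (chromosome 2, 69355470 to 69355735, signal 51.3), Frmd4a (41.8), G6pd2 (36.3) and Gm5426 (35.6). Those nearest to Galc, Hic2, Myl12b, Limd1 and Tyrp1 had signals of 29.96, 26.9, 26.8, 26.5 and 26.2. The start sites of G6pd2, Galc and Tyrp1 lay 1766, 1198 and 831 kb away, so these intervals were not assigned to a gene. The interval nearest to Limd1 overlapped an exon of the mitochondrial leucyl-tRNA synthetase gene Lars2. Of these 10 intervals, the 5 nearest to Abcb11, G6pd2, Gm5426, Galc and Tyrp1 matched the mitochondrial genome.

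Sequence motifs were counted at distal summits to ask which DNA-binding factors have sites there. CTCF, which anchors chromatin loops and boundaries, had a site at 7.45% of 10009 distal summits against 0.0831% of flanking windows. The ratio was 89.7 (95% interval 54.9 to 158). Within 50 bp of the summit it was 208.3, on a control share of only 0.0258%. The RFX motif, bound by a family that includes regulators of ciliary genes, stood at 3.15% against 0.114% (ratio 27.5, 17.9 to 44.6). Its ratio within 50 bp was 51.3, on a control share of 0.0465%. Both ratios within 50 bp rest on few control matches and have no interval. The palindrome of the NFI family, to which Nfia and Nfib belong, stood at 0.949% against 0.130% (ratio 7.31, 4.67 to 11.9). The E-box of ASCL1 and related factors stood at 24.4% against 8.90% (ratio 2.74, 2.57 to 2.92). SOX sites stood at 12.9% against 7.31% (ratio 1.77) and the POU octamer at 7.47% against 4.56% (ratio 1.64). The E-box of NEUROG and NEUROD factors had a ratio of 1.26 and the homeodomain motif of LHX, DLX and EMX factors 1.43. The GATA motif, bound by blood and endothelial regulators, was less frequent than in flanks (1.96% against 4.37%, ratio 0.448), as was that of the liver factor HNF4 (ratio 0.508, 0.260 to 0.929).

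In the sets of replicate 1 and replicate 2 alone the CTCF ratio was 70.7 and 44.3, that of NFI 17.6 and 10.4 and that of the homeodomain motif 2.02 and 1.39. The CTCF and NFI ratios of the replicates also rest on few control matches. In all, 13 of 27 motifs reached a ratio of 1.5. The others above it were SP/KLF at 8.25, CREB at 5.33, ETS at 3.57, NFY at 2.47, PBX at 1.86, NRF1 at 20.2 on 2 control matches (4.94 to 178) and YY1 at 4.49 as a lower bound on 0 control matches. In replicate 2 alone CREB had 8.30, and NRF1 had at least 10.2 on 0 control matches. At promoters the ratios of ETS, SP/KLF and CREB, common motifs of broadly active promoters, were 42.3, 30.3 and 24.5, and that of CTCF was 7.52. Higher promoter ratios rested on few control matches: YY1 had 308 on 1 match and NRF1 at least 133 on 0. Distal summit windows had a mean GC content of 53.9% and flanks 44.7%. Against windows matched on GC 15 motifs reached a ratio of 1.5. The homeodomain ratio was 4.07, NRF1 6.55, MEF2 2.06 against 0.905 with flanks, and FOX 1.35 against 0.806. POU had 3.37, SP/KLF 3.44, CREB 3.45, ETS 2.46, NFY 1.66 and the ASCL1 E-box 1.77. GATA had 0.633 against 0.448 with flanks, and the HOX posterior motif 0.992 against 0.434.

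**Figure D3:**
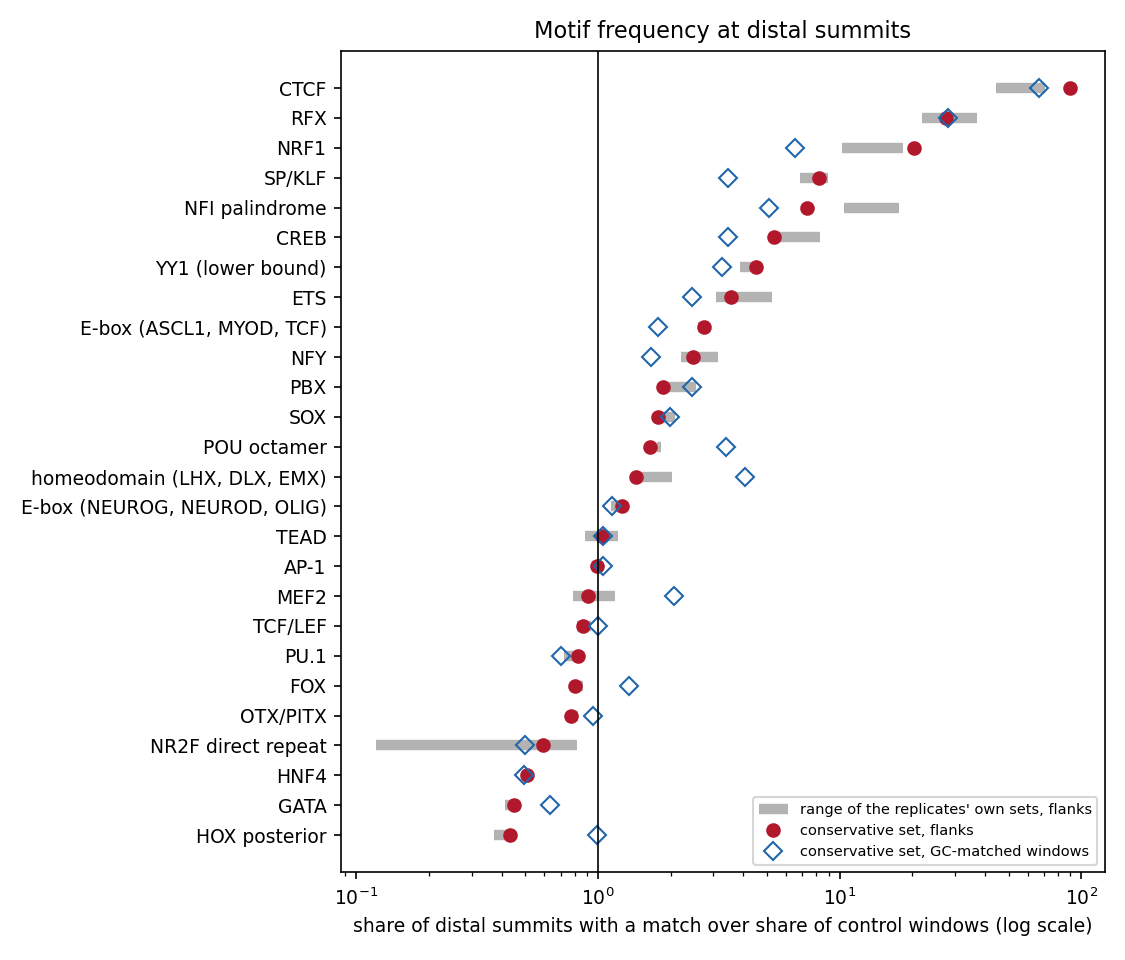
Ratio of the share of distal summits with a motif match to the share of control windows (log axis), for each motif with a ratio. Circles use flanking windows and diamonds GC-matched windows for the conservative set, and grey bars span the replicates' own sets, with lower bounds for YY1 and, in replicate 2, NRF1; CTCF at 89.7 and RFX at 27.5 lie highest.

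Replicates were compared to ask how far each region was seen in both pools. Replicate 1 gave 22782 IDR-thresholded intervals and replicate 2 gave 15568, a ratio of 1.46. Distal intervals numbered 10488 and 4455, and promoter intervals 12294 and 11113. Of replicate 2 intervals, 93.5% overlapped replicate 1 (95% interval 93.1 to 93.9; 1.81% after shifting). Of replicate 1 intervals, 63.7% overlapped replicate 2 (63.0 to 64.3; 1.24% after shifting), and 90.5% overlapped its longer pseudoreplicated list. Among intervals of the pooled pseudoreplicated list, replicate 1 called 92.3% of promoter and 71.5% of distal intervals, and replicate 2 called 85.4% and 42.7%.

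The strongest intervals called in replicate 1 alone lay nearest to Intu, a ciliogenesis gene (chromosome 3, 40102510 to 40103183, signal 15.3), and in an intron of the zinc transporter gene Slc39a10 (chromosome 1, 46829900 to 46831087, signal 13.5). The others lay nearest to Rgs9 (11.9), in an intron of the growth factor receptor gene Fgfr2 (nearest start site Cpxm2, 11.7) and nearest to Tex13c2 (11.6). Those called in replicate 2 alone were weaker, with signals of 6.57 to 6.86, nearest to Stac, Ubac1, Fam107a, Speer4d and Pknox1.

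Over 31359 shared intervals the signals of the replicates had a Spearman correlation across peaks of 0.838. It was 0.912 over 14109 promoter intervals and 0.648 over 17250 distal ones. The median log2 ratio of signal, replicate 2 over replicate 1, was -0.24. Relative to that median, housekeeping genes were the 1 list of 18 outside the range of random peak sets, with a median of 0.19 over 32 peaks, at percentile 99.7; chance gives 0.9 lists. At distal peaks alone the housekeeping list was inside the range (percentile 94.8). There the endothelial list (0.21 over 12 peaks, percentile 99.8) and the neural progenitor list (0.01 over 140 peaks, percentile 97.8) lay above it. The pallial, subpallial and neuronal lists lay inside it in both comparisons, with percentiles of 15.8, 55.03 and 34.8 over all shared peaks.

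**Figure D4:**
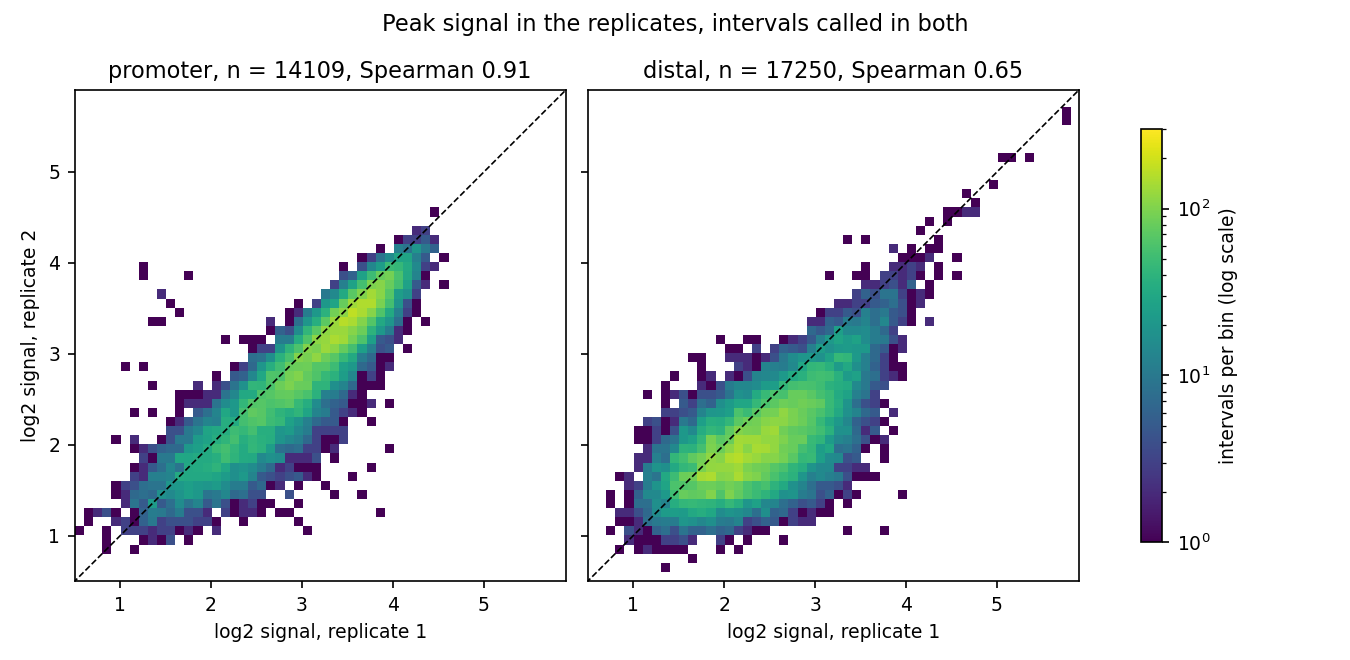
Signal of shared intervals in replicate 2 against replicate 1, both on log2 axes, for promoter (left, n = 14109) and distal intervals (right, n = 17250); colour gives intervals per bin on a log scale and the dashed line is equality. Of all shared intervals 78.2% lie below the line; 15 lie more than 1.5 log2 units above the median ratio, and 0 do when only summits inside the interval are used.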

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

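The tests of the 8 distal and 12 promoter intervals in this part were chosen only after the result was seen. Of 64478 peaks in the ranked list of the true replicates with a score of at least 540, 264 had no match in the thresholded list. These drew attention because no comparison used them. Of the 264, 90 lay on unplaced scaffolds, which had been removed from the thresholded list before matching. Whether that list leaves these 90 out is therefore unknown. The 264 peaks formed 105 intervals, 34 on unplaced scaffolds and 71 on chromosomes. The strongest lay nearest to the collagen gene Col19a1 (chromosome 1, 24611586 to 24616165) with a −log10 p of 6709, and matched the mitochondrial genome at 99.956% identity over 4580 bp. The next lay nearest to the neural adhesion gene Chl1 (chromosome 6, 103648978 to 103649356) with a −log10 p of 5249 and did not match. Many of the others lay close together. Several nearest to Gm21738 lay between 19415649 and 19419478 on chromosome 14, and several nearest to Gm10717 between 3025440 and 3032680 on chromosome 9. The sources used here do not say why peaks were left out. Of the 71 intervals on chromosomes, 1 matched.

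The strongest intervals of the conservative set lay far above the rest, with a −log10 p of 7607 nearest to Galc and 4278 in an intron of Myo3a near Gad2, against a median of 79.9. Reads of mitochondrial DNA placed at nuclear copies of mitochondrial sequence could account for part of this: 6 of the 20 strongest intervals matched the mitochondrial genome, against 6 of the other 22727, which is above the bound of 5 set against this explanation but not most of them. By position, 6 of the 8 distal intervals among the 20 matched, and 0 of the 12 at promoters did. This argues against long and close copies at promoters such as Zfp654, Pja2 and Hmgb2. Copies shorter or less similar than the matching rule requires would be missed, so the explanation is not excluded there. It remains open for the distal intervals. The intervals nearest to Pak3 and Limd1 were the 2 distal ones that did not match. No biological explanation was tested, since the design has 1 group.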

How the results depend on the processing

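CpG-rich promoters, leaving out mitochondrial matches and summits inside the interval were chosen after seeing the data. Of 37 alternatives of the main results, 17 kept their value within its interval or within 1.5 times its count; for the others the cause was not tested. The share of replicate 2 intervals found in replicate 1 was 89.8% with 50% reciprocal overlap, 83.1% with summits within 100 bp, 77.5% with equal numbers of intervals and 86.1% with pseudoreplicated lists; the share of replicate 1 found in replicate 2 was 61.3%, 56.8%, 77.0% and 58.5%. The correlation of strength was 0.856 with −log10 p, 0.648 over distal peaks, 0.388 without the stronger peaks and 0.843 with only summits inside the interval. The promoter share of summits was 57.9% within 2.5 kb, 47.0% in the pooled IDR set, 27.2% in the replicated set, and 52.6% to 70.1% when either replicate was left out. With stronger-signal intervals only, 2 lists passed the distal test, not 4; with CpG-rich promoters 5 passed the promoter test, not 14, and no list could pass there with more; at distal peaks 2 lists, not 1, lay outside the range between replicates. Leaving out a replicate gave 4 to 5 lists in the distal test, 11 to 14 in the promoter test and 13 to 14 motifs. Of 55 named genes, 36 had distal counts beyond 1.5 times the main count without replicate 1 and 12 without replicate 2. Among lists past the promoter test, differences that changed sign were pallial without replicate 1 (-1.38 points, against 22.6 without replicate 2) and, in CpG-rich promoters, subpallial (-8.99 points) and myeloid (8.67 points, 1 gene). Among the others, diencephalic was at -7.63 points without replicate 1 and -11.3 in CpG-rich promoters, where mature glial was at 8.68, and the replicated set gave mid- and hindbrain 8.56 and mesenchyme 18.7 points. In the distal test 9 lists that did not pass changed sign under at least 1 alternative, and the median per gene gave 5 lists, not 4. Leaving out mitochondrial matches kept the same 4 lists. No paired analysis was possible because there is 1 group. Yield, overlap, strength and the replicate difference need both libraries, and unknown read numbers limit what weak peaks show.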

Other observations

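The test of depth in this part was chosen only after the result was seen, as were the distal intervals with the most unequal signal. Lists differed in how many of their distal intervals in the pooled pseudoreplicated list each library called, against 71.5% in replicate 1 and 42.7% in replicate 2 over all distal intervals. Of 284 at neural progenitor genes, replicate 1 called 78.2% and replicate 2 57.7%. Of 216 at pallial genes the shares were 76.4% and 41.2%, and of 204 at subpallial genes 71.1% and 52.0%. Diencephalic genes had 72.0% and 50.8%, neuronal genes 71.7% and 50.2%, mesenchymal genes 64.9% and 32.5% and mature glial genes 76.7% and 34.9%. Endothelial genes had 55.6% and 33.3% of 45. Housekeeping genes had 66.7% and 63.0% of 27. Skeletal muscle genes were called slightly more often in replicate 2, with 13 and 15 of 27 (48.1% and 55.6%). The differences between lists were not tested.

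Among shared distal intervals with a summit of each replicate inside, the lowest ratio of replicate 2 over replicate 1 lay nearest to Ppp1r3a (chromosome 6, 14600398 to 14601219; signal 15.4 and 2.68, log2 ratio -2.52). An interval 239.4 kb from the start site of Emx2, a transcription factor gene of the pallium, had signals of 10.6 and 2.68 (chromosome 19, 59697401 to 59698192, log2 ratio -1.98). Prkg2, Arrdc4 and Galnt18 were nearest to the others of the lowest 5, at -2.04, -1.97 and -1.96. The highest ratios were nearest to Chst8 at 1.22 and the transcription factor gene Zfhx3 at 1.19. With the strongest overlapping value in place of summits inside the interval, 15 intervals lay more than 1.5 log2 units above the median ratio and 32 below it; with summits inside, 0 lay above and 21 below.

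Replicate 2 gave fewer peaks than replicate 1. Lower sequencing depth is argued against by the background per position, which was 1.02 times that of replicate 1. More tissue of several other kinds together in replicate 2 is argued against, though weakly, by the other-tissue lists at distal peaks. Among those of the 6 lists that could be tested, 1, endothelial, lay above the range of random peak sets. Surface ectoderm rested on 7 peaks, with a random range of -0.48 to 0.22, and myeloid on 15, with -0.37 to 0.13. A modest excess could be missed there. Erythroid, with 2 shared distal peaks, had too few to test. The bound required several lists to lie above the range, so this test cannot decide on more tissue of 1 kind, such as vessel, which remains open. Lower enrichment over background in replicate 2 remains open as a candidate explanation: its excess of tags was lower at 87.4% of shared promoter and 83.2% of shared distal peaks. With a like background, fewer called peaks and a lower excess describe the same tags, so these shares are not independent support. The pools also came from 120 and 68 embryos, and whether this matters was not tested.

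Some of the 168 genes in the 11 lists of other tissues had an accessible promoter. CpG-rich promoters that are open in most tissues may account for this: 23 of 65 CpG-rich promoters (35.4%, 95% interval 23.9 to 48.2) and 11 of 103 others (10.7%, 5.45 to 18.3) were accessible. The difference of 24.7 percentage points lay between the bounds set for and against this explanation, so it stays open. Most CpG-rich promoters of these genes were not accessible, whereas 91.3% of all CpG-rich promoters were. No biological explanation was tested.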
